A study of Danio rerio with 4 samples.

How the data were processed

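Poly-A RNA from whole wild-type zebrafish embryos was measured in 4 libraries, 2 control and 2 from embryos exposed to SYP-3343 at 8 µg/L from 3 to 24 hpf. The labels call the libraries of each group biological replicates 1 and 2. Whether the 40 embryos of the design text stand for a library or a group is not given in the sources used here. Per the labels, RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra kit after selection on poly-T beads. The deposited table gives the authors' counts of reads per gene, whole numbers without normalization. Per the submitters' processing notes, TopHat2, HISAT2, HTSeq, featureCounts 1.6.2 and DESeq2 1.14.1 were used with the genome build GRCz11, with no role or order stated. The annotation and the strand setting of the counting are not given in the sources used here. All 4 columns of counts were used.

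The table held 28290 gene models, of which 25430 had Ensembl identifiers (23607 with a symbol) and 2860 were models added to the annotation. All 4 libraries were at 0 for 2373 models, and 1746 symbols were shared by several identifiers, which are then named with the identifier. The library totals were 46165614 and 59054470 counts in control replicates 1 and 2, and 49075203 and 49962016 in SYP-3343 replicates 1 and 2. A count of 0 allows up to 3 counts, or 0.0508 to 0.065 CPM, and such floors cover counting error only.

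Genes were kept by edgeR's filterByExpr with its defaults, scaled by TMM (factors 1.11 and 1.14 for the controls, 0.923 and 0.86 for SYP-3343) and tested two-sided with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05 over the 22647 genes tested. The biological coefficient of variation was 10.1%. Lists of genes were tested with limma's camera on log2 CPM with a prior count of 2 and a correlation of 0.01 between genes, and adjusted over the 43 lists. The lists held 1710 symbols, of which 1312 matched by symbol, 300 by the capital form of the name and 36 by a map made by hand, while 62 did not match, which gave 1746 gene identifiers. Correlations between libraries are across genes on log2 CPM with 1 added, and genes are not independent replicates. Intervals of list medians are 95% bootstrap intervals over the members, from 2000 resamples.

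Genes were named by a rule: the 12 largest rises and the 12 largest falls by log2 fold change among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, a symbol, and both SYP-3343 libraries on one side of both controls, and up to 4 tested members of each list with the smallest adjusted p. A gene named by both parts counts under both. Some genes that the rule names are not reported here. Genes outside the rule are named where a copy, a small count or an added list called for it, after their values were seen. The groups, tests, lists, naming rule and alternatives were chosen before the data were examined. Added after the data were seen were 4 lists (photoreceptor genes, early retina genes, and cytosolic and mitochondrial aminoacyl-tRNA synthetases), used in the closing section alone.

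The alternatives were RLE and upper-quartile factors, library size alone, no low-count filter, a CPM of at least 1 in at least 2 libraries, DESeq2's Wald test, limma-voom, robust estimation of the quasi-dispersion, the legacy quasi-likelihood fit, the replicate number as a block, leaving out the 20 most abundant genes, leaving out each library in turn, an adjusted p of 0.01, and an absolute log2 fold change of at least 1. Lists were also tested with an estimated correlation and with fry, which asks if the genes of a list move one way without comparing them with other genes. A library left alone in its group was assumed to vary like the other group. The code was tested on simulated data with known changes, where 22554 genes were tested. It called 47 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold. There were 11 false calls and 0 errors of sign. Beside these genes only the mitosis list was raised, and it was called. The simulated changes were few and of random sign, without the difference in composition seen between the real groups. The simulation thus cannot speak for false calls or signs that depend on the scaling. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.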

Results

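RNA was sequenced from whole wild-type zebrafish (*Danio rerio*) embryos, in 2 control libraries and 2 libraries from embryos exposed to SYP-3343, a compound named here by its code. The exposure was 8 µg/L from 3 to 24 hours post-fertilization (hpf), and the design text speaks of 40 embryos collected. The title of the series sets the question as developmental toxicity by way of reactive oxygen species and damaged mitochondria. The libraries held 46165614 and 59054470 counts in control replicates 1 and 2, and 49075203 and 49962016 in SYP-3343 replicates 1 and 2. Log2 CPM values correlated across genes with r = 0.995 within each group, and with r from 0.978 to 0.979 between libraries of different groups. The 20 most abundant genes took 10.23% and 10.28% of the counts in the control libraries and 14.6% and 15.4% in the SYP-3343 libraries, and mitochondrial genes took 2.95% and 2.76% in controls and 2.404% and 2.499% in SYP-3343. The labels call the libraries biological replicates without saying from which clutches or tanks they came, so p-values measure the spread between these samples.

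In exposed embryos, 70 of 71 tested genes for cytosolic ribosomal proteins and 37 of 42 genes of the integrated stress response rose. So did 33 of 56 genes of epidermis, ionocytes and hatching gland and 32 of 61 of neural progenitors and glia. Of sterol and fatty acid synthesis genes 26 of 36 fell, as did 32 of 66 early neuron genes and 21 of 45 genes of notochord, cartilage and sheath, and 3 cone opsins were among the largest falls. The calls of these 7 lists ended with an estimated correlation (adjusted p from 0.333 to 0.686), a test with little power at 2 libraries per group. With edgeR's quasi-likelihood test, 7225 of 22647 tested genes (31.9%) passed an adjusted p of 0.05, of which 3770 were higher in SYP-3343 and 3455 lower. A change of at least 2-fold was found for 746 higher and 746 lower genes, and one of at least 4-fold for 140 higher and 214 lower genes. The split of the calls depended on the scaling. It was 52.2% higher with TMM factors, 40.5% with upper-quartile factors (3042 higher and 4462 lower) and 13% with library sizes alone (1405 higher and 9384 lower). Library sizes alone moved the median log2 fold change of all genes to -0.35 from -0.01, and turned the medians of these uncalled lists from above to below 0: complexes IV and V, mitochondrial biogenesis, Nrf2 targets, superoxide and glutathione enzymes, glycolysis, yolk, tailbud, skeletal muscle, pigment cells, germ cells and mitochondrial ribosomal proteins. Upper-quartile factors turned that of mitochondrial biogenesis, and RLE factors those of heart muscle and of collagens.

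Among named genes, the largest rise was that of *isg15*, a ubiquitin-like protein induced by interferon. *isg15* (ENSDARG00000086374) rose from 0.498 ± 0.0121 to 31.7 ± 4.98 CPM (log2 fold change 5.99 ± 0.20, adjusted p = 1.12e-14), a 63.4-fold difference (CPM values are TMM-normalized means ± SD, and log2 fold changes are given ± SE, with n = 2 per group). *irf3* (ENSDARG00000076251) rose from 0.65 ± 0.365 to 7.10 ± 1.11 CPM (log2 fold change 3.38 ± 0.28, adjusted p = 6.57e-09), and its product is a transcription factor of the interferon response. *ucp3* (ENSDARG00000091209) rose from 1.56 ± 0.287 to 15.4 ± 0.162 CPM (log2 fold change 3.32 ± 0.18, adjusted p = 1.01e-11), and encodes a carrier of the inner mitochondrial membrane of the uncoupling protein family. The transcription factor gene *atf5b* (ENSDARG00000077785) rose from 32 ± 3.91 to 279.6 ± 50.2 CPM (log2 fold change 3.13 ± 0.12, adjusted p = 8.14e-14). *CYP24A1* (ENSDARG00000103277) rose from 2.17 ± 0.419 to 19.7 ± 4.28 CPM (log2 fold change 3.16 ± 0.18, adjusted p = 2.32e-11), and encodes the enzyme that breaks down active vitamin D. Of the monocarboxylate transporter family, *SLC16A6* copy ENSDARG00000060246 (3.29 ± 0.11) and *SLC16A9* copy ENSDARG00000104687 (3.13 ± 0.10) rose 9.79-fold and 8.74-fold. The arrestin-domain gene *ARRDC3* copy ENSDARG00000036028 (3.08 ± 0.11) rose from 30.6 to 258.5 CPM, and *tcap* (2.87 ± 0.11), which encodes the sarcomere protein telethonin, from 9.14 to 66.8 CPM. The other genes of this rank were the transporter gene *MFSD4A* copy ENSDARG00000008263 (3.82 ± 0.22), the rhomboid protease gene *RHBDD1* (2.83 ± 0.16) and *OCIAD2* (2.78 ± 0.12).

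The largest falls among named genes included 3 cone opsins. *OPN1SW* (ENSDARG00000045677) fell from 11.8 ± 5.12 to 0.369 ± 0.291 CPM (log2 fold change -4.95 ± 0.39, adjusted p = 3.02e-09), and *opn1lw2* (ENSDARG00000044861) fell from 27.6 ± 7.71 to 1.3 ± 0.192 CPM (log2 fold change -4.39 ± 0.21, adjusted p = 2.72e-12). *opn1sw2* (-2.93 ± 0.33) fell 7.60-fold. Phototransduction genes fell beside them, with the cone transducin subunit *GNGT2* copy ENSDARG00000103543 (-3.94 ± 0.53) and the arrestin *sagb* (-2.95 ± 0.21). With robust estimation of the dispersion, the call of this *GNGT2* copy ended (adjusted p = 0.0908, the highest of its alternatives, the lowest being 1.85e-19). *MATN1* (ENSDARG00000030215) fell from 225 ± 47.8 to 22.9 ± 0.345 CPM (log2 fold change -3.29 ± 0.13, adjusted p = 6.44e-14), and encodes matrilin, a protein of cartilage matrix. The myelin basic protein gene *mbpa* fell to 16 counts in the SYP-3343 libraries from 476 in the controls (log2 fold change -4.47 ± 0.44). *FADS3* (ENSDARG00000019532) fell from 15.3 ± 1.5 to 1.53 ± 0.00925 CPM (log2 fold change -3.32 ± 0.18, adjusted p = 1.56e-11), and belongs to the fatty acid desaturase family. The others were *itih3a.2* (-3.73 ± 0.44), *lactbl1a* (-3.00 ± 0.30), *lypc* (-2.75 ± 0.20) and *cox4i1l* (-2.78 ± 0.25), a paralog of subunit 4 of cytochrome c oxidase. The plot of normalized CPM per library shows these genes.

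**Figure D1:**
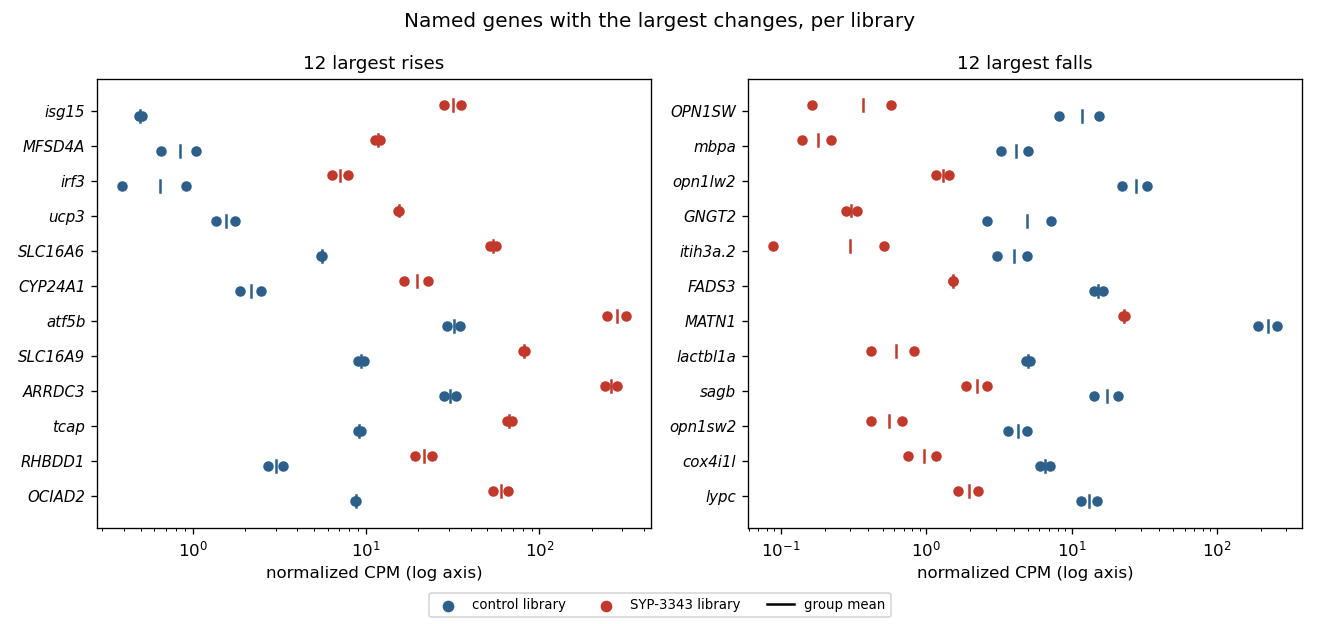
Normalized CPM on a log axis for the 12 named genes with the largest rise (left) and the 12 with the largest fall (right), with points for single libraries (blue control, red SYP-3343, 2 per group) and vertical bars for group means. In each gene both SYP-3343 libraries lie on one side of both control libraries, as the rule for naming requires, and *isg15* rises from 0.498 to 31.7 CPM.

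Gene lists fixed before the data were examined were tested with limma's camera. With the correlation between genes preset at 0.01, 19 of the 43 lists were called higher and 4 lower. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.333 and 4 lists had an unadjusted p under 0.05, while fry called 7 lists. Calls were lost even where the estimate was below 0.01, as for sterol synthesis (-0.023), ribosome biogenesis (-0.012) and early neurons (-0.012). With an estimated correlation camera's threshold rests on the number of libraries, so at 2 per group few lists could pass whatever their correlation. For each of the 23 called lists the estimated correlation gave the highest adjusted p of the 9 alternatives. Below, a gene is said to have risen or fallen where its edgeR adjusted p was under 0.05, and the value after its name is the log2 fold change, SYP-3343 minus control, ± its SE. List medians and means are on the same scale.

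**Figure D2:**
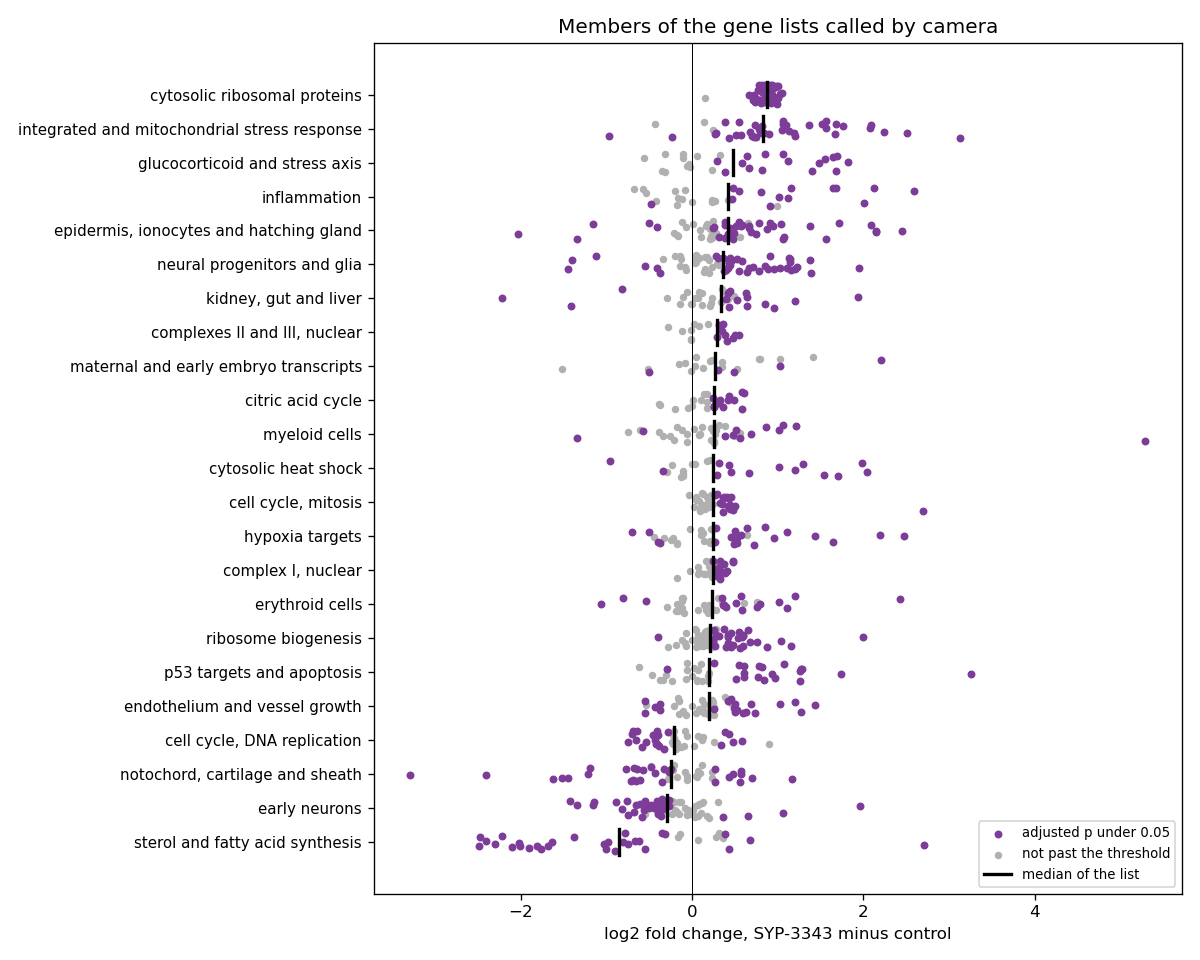
Log2 fold change (SYP-3343 minus control) of each tested member of the 23 lists called by camera with a preset correlation, with points for genes, purple where the adjusted p was under 0.05 and grey otherwise, spread vertically at random, and black bars for list medians. Cytosolic ribosomal proteins lie in a narrow band around 0.88, and sterol and fatty acid synthesis has the lowest median, -0.85, while with library sizes alone 13 of the 19 medians above 0 fall below 0.

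The respiratory chain, named by the series' title through mitochondrial function, changed in parts. Of the protein-coding genes of the mitochondrial genome, 2 of 13 tested members rose, 4 fell and 7 did not pass (2 rose and 4 fell adjusted over the list alone). The mitochondrial genome list had a median of -0.15 (camera adjusted p = 0.249) and was not called. The falls were *mt-atp8* (-0.81 ± 0.11), *MT-ATP6* (-0.75 ± 0.14), *MT-ND5* (-0.68 ± 0.11) and *mt-nd4l* (-0.51 ± 0.095). *mt-atp8* and *MT-ATP6* overlap on the genome, as do *mt-nd4l* and its neighbour, so reads cannot be fully told apart. For nuclear genes of complex I, 15 of 38 tested members rose, 0 fell and 23 did not pass (21 rose and 0 fell adjusted over the list alone). The complex I list had a median of 0.24 (camera adjusted p = 0.000237, adjusted p = 0.829 with an estimated correlation) and one of -0.09 with library sizes alone. Risers included *NDUFA2* (0.48 ± 0.10), *NDUFA6* (0.47 ± 0.11), *NDUFB8* (0.41 ± 0.10) and *NDUFS7* (0.38 ± 0.097). For complexes II and III, 9 of 17 tested members rose, 0 fell and 8 did not pass (9 rose and 0 fell adjusted over the list alone). The complex II and III list had a median of 0.29 (camera adjusted p = 0.0247, adjusted p = 0.829 with an estimated correlation) and one of -0.04 with library sizes alone. Its risers included *uqcrc2a* (0.55 ± 0.096), *UQCRB* (0.50 ± 0.096), *CYC1* (0.48 ± 0.095) and *SDHC* (0.40 ± 0.094). Without control replicate 2 or SYP-3343 replicate 2 the call of complexes II and III ended (adjusted p = 0.109 and 0.165, 0.0073 to 0.829 over its alternatives). For complexes IV and V, 10 of 36 tested members rose, 4 fell and 22 did not pass (11 rose and 4 fell adjusted over the list alone). The complex IV and V list had a median of 0.17 (camera adjusted p = 0.162) and was not called, but was without control replicate 1 or SYP-3343 replicate 1 (adjusted p = 0.0129 and 0.0358, 0.0129 to 0.843 over its alternatives). There *cox4i1l* (-2.78 ± 0.25) and *cox6b1* (-0.86 ± 0.11) fell, while *atp5mc3b* (0.53 ± 0.11) and *COX4I1* (0.49 ± 0.11) rose. With library sizes alone the calls of these complex I, II, III, IV and V genes ended, except *cox4i1l* and *cox6b1*. Without SYP-3343 replicate 2, those of *NDUFB8* (adjusted p = 0.0605, 0.000152 to 0.525 over its alternatives) and *NDUFS7* (adjusted p = 0.0956, 0.000661 to 0.712) ended too.

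Of mitochondrial biogenesis and dynamics genes, 11 of 33 tested members rose, 4 fell and 18 did not pass (11 rose and 4 fell adjusted over the list alone). The biogenesis list had a median of 0.02 (camera adjusted p = 0.344) and was not called. The carriers *ucp3* (3.32 ± 0.18), *UCP1* (1.66 ± 0.10) and *SLC25A5* (1.21 ± 0.16) and the outer membrane channel gene *VDAC2* (0.86 ± 0.11) rose. In the citric acid cycle, 13 of 24 tested members rose, 0 fell and 11 did not pass (13 rose and 0 fell adjusted over the list alone). The citric acid cycle list had a median of 0.25 (camera adjusted p = 0.00383, adjusted p = 0.686 with an estimated correlation) and one of -0.09 with library sizes alone. *FH* copy ENSDARG00000075132 (0.60 ± 0.091), *MDH2* (0.58 ± 0.098), *IDH2* (0.59 ± 0.11) and *MDH1* (0.49 ± 0.098) rose, *MDH1* not with library sizes alone. Glycolysis genes went both ways, and 12 of 37 tested members rose, 8 fell and 17 did not pass (12 rose and 8 fell adjusted over the list alone). The glycolysis list had a median of 0.14 (camera adjusted p = 0.382). There *LDHB* (0.80 ± 0.12) rose, and *PFKL* copy ENSDARG00000099755 (-0.79 ± 0.11) fell. For fatty acid oxidation, 6 of 35 tested members rose, 8 fell and 21 did not pass (7 rose and 8 fell adjusted over the list alone). The fatty acid oxidation list had a median of -0.03 (camera adjusted p = 0.784) and a mean of 0.04. *PDK2* copy ENSDARG00000059054 (1.93 ± 0.13) and *PDK2* copy ENSDARG00000020876 (1.19 ± 0.095), which encode kinases that inhibit pyruvate dehydrogenase, and the carnitine palmitoyltransferase *cpt1ab* (0.61 ± 0.091) rose, and *CPT2* (-0.76 ± 0.13) fell.

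Of superoxide, peroxide and glutathione enzymes, a list that holds NADPH oxidases beside enzymes that remove reactive oxygen species, 7 of 33 tested members rose, 5 fell and 21 did not pass (7 rose and 5 fell adjusted over the list alone). The superoxide and glutathione list had a median of 0.11 (camera adjusted p = 0.522). The superoxide dismutase gene *SOD1* (-0.76 ± 0.11), the catalase gene *CAT* (-0.64 ± 0.093) and the glutathione peroxidase *gpx4a* (-0.70 ± 0.11) fell, while the peroxiredoxin *prdx5* (0.63 ± 0.094) rose. Related genes, named after their values were seen, did not all follow. *SOD2* (0.17 ± 0.10) did not pass and the other copy of the peroxidase, *GPX4* (0.36), rose, while *SOD3* copy ENSDARG00000079183 (-1.63) fell. Of Nrf2 targets, 11 of 31 tested members rose, 8 fell and 12 did not pass (11 rose and 8 fell adjusted over the list alone). The Nrf2 list had a median of 0.09 (camera adjusted p = 0.444). The Nrf2 paralog *nfe2l2b* (2.75 ± 0.15) rose 6.74-fold, and *KEAP1* (1.06 ± 0.094) and *TCIRG1* copy ENSDARG00000105142 (0.86 ± 0.095) rose, while the glutathione transferase *gstp1.1* (-1.94 ± 0.22) fell. Of xenobiotic metabolism genes, 9 of 41 tested members rose, 15 fell and 17 did not pass (10 rose and 18 fell adjusted over the list alone). The xenobiotic metabolism list had a median of -0.23 (camera adjusted p = 0.212). *cyp3c1* (0.89 ± 0.12), *POR* copy ENSDARG00000059035 (0.70 ± 0.11) and *ABCB4* (0.87 ± 0.14) rose, and *CYP1A1* (-0.90 ± 0.14), a target of the aryl hydrocarbon receptor, fell from 13.9 to 7.48 CPM.

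The integrated and mitochondrial stress response, in which ATF4-type factors raise amino acid synthesis and transport genes, was higher, and 37 of 42 tested members rose, 2 fell and 3 did not pass (38 rose and 2 fell adjusted over the list alone). The stress response list had a median of 0.83 (camera adjusted p = 2.35e-15, adjusted p = 0.333 with an estimated correlation) and one of 0.50 with library sizes alone. Its leading members were *atf5b* (3.13 ± 0.12), *sesn2* (2.51 ± 0.11), *TRIB3* (2.08 ± 0.096) and *AARS1* (2.24 ± 0.11). Of p53 targets and apoptosis genes, 19 of 39 tested members rose, 1 fell and 19 did not pass (19 rose and 2 fell adjusted over the list alone). The p53 list had a median of 0.20 (camera adjusted p = 0.000658, adjusted p = 0.785 with an estimated correlation) and one of -0.13 with library sizes alone. *GADD45B* copy ENSDARG00000027744 (1.74 ± 0.12), *rps27l* (1.26 ± 0.11) and *CASP9* (1.28 ± 0.15) rose. Of cytosolic heat shock genes, 12 of 24 tested members rose, 2 fell and 10 did not pass (12 rose and 3 fell adjusted over the list alone). The heat shock list had a median of 0.25 (camera adjusted p = 0.00837, adjusted p = 0.675 with an estimated correlation) and one of -0.09 with library sizes alone. *hsp70.3* (1.98 ± 0.11), *SERPINH1* copy ENSDARG00000019949 (2.05 ± 0.11), *HSP90AA1* (1.54 ± 0.10) and *HSPH1* (1.70 ± 0.21) rose, the first of them in a cluster of near-identical copies. The endoplasmic reticulum list was not called, and 6 of 27 tested members rose, 8 fell and 13 did not pass (6 rose and 10 fell adjusted over the list alone). The endoplasmic reticulum stress list had a median of -0.15 (camera adjusted p = 0.413). There *atf6* (1.06 ± 0.096) and *XBP1* (1.04 ± 0.10) rose, and the chaperone genes *PDIA4* (-0.75 ± 0.092) and *dnajc3b* (-0.68 ± 0.11) fell.

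Of hypoxia targets, 18 of 38 tested members rose, 4 fell and 16 did not pass (18 rose and 4 fell adjusted over the list alone). The hypoxia targets list had a median of 0.24 (camera adjusted p = 0.00394, adjusted p = 0.675 with an estimated correlation) and one of -0.09 with library sizes alone. *IGFBP1* (2.47 ± 0.10), *PFKFB3* (2.19 ± 0.12), *higd1a* (1.64 ± 0.097) and *VEGFA* copy ENSDARG00000103542 (1.44 ± 0.11) rose. Of the glucocorticoid and stress axis, 16 of 28 tested members rose, 0 fell and 12 did not pass (16 rose and 0 fell adjusted over the list alone). The glucocorticoid list had a median of 0.48 (camera adjusted p = 0.000349, adjusted p = 0.675 with an estimated correlation) and one of 0.15 with library sizes alone. *FKBP5* (1.69 ± 0.092), *CEBPD* (1.69 ± 0.11), *PCK1* (1.39 ± 0.092) and *sgk2b* (1.82 ± 0.13) rose, and *CEBPD* also belongs to the inflammation list. Of inflammation genes, 13 of 29 tested members rose, 1 fell and 15 did not pass (13 rose and 1 fell adjusted over the list alone). The inflammation list had a median of 0.42 (camera adjusted p = 0.0176, adjusted p = 0.675 with an estimated correlation) and one of 0.09 with library sizes alone. The AP-1 gene *FOSL1* (2.59 ± 0.18) rose, and *SOCS3* copy ENSDARG00000026611 (1.12 ± 0.12) and *SOCS3* copy ENSDARG00000025428 (1.65 ± 0.18) rose. Of circadian clock genes, 11 of 39 tested members rose, 7 fell and 21 did not pass (11 rose and 7 fell adjusted over the list alone). The clock list had a median of -0.10 (camera adjusted p = 0.982) and a mean of -0.02, with a test direction above 0. *PER1* copy ENSDARG00000012499 (0.85 ± 0.096), *nr1d2a* (0.83 ± 0.097) and *ciarta* (0.70 ± 0.090) rose, and *dbpa* (-1.0 ± 0.16) fell.

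In the translation machinery, 70 of 71 tested members rose, 0 fell and 1 did not pass (70 rose and 0 fell adjusted over the list alone) among genes for cytosolic ribosomal proteins. Their median log2 fold change was 0.88, the camera adjusted p was 1.36e-23, and adjusted p = 0.675 with an estimated correlation, which was 0.91 between these genes. With library sizes alone the ribosomal protein median was 0.54. *RPL39* (1.03 ± 0.11), *RPL38* (0.85 ± 0.094), *RPS28* (0.86 ± 0.10) and *RPL11* (1.05 ± 0.13) led the list, and *RPL11* went from 948 ± 87.4 to 1958 ± 218.8 CPM. Of ribosome biogenesis genes, 28 of 67 tested members rose, 1 fell and 38 did not pass (29 rose and 1 fell adjusted over the list alone). The ribosome biogenesis list had a median of 0.21 (camera adjusted p = 1.81e-06, adjusted p = 0.333 with an estimated correlation) and one of -0.12 with library sizes alone. *DDX21* (1.99 ± 0.11), *BOP1* (1.15 ± 0.097), *HEATR1* (1.03 ± 0.093) and *UTP4* (0.88 ± 0.098) rose. Of mitochondrial ribosomal proteins, 13 of 75 tested members rose, 1 fell and 61 did not pass (7 rose and 1 fell adjusted over the list alone). The mitochondrial ribosome list had a median of 0.07 (camera adjusted p = 0.0609) and was not called, but was without control replicate 1 or SYP-3343 replicate 1 (adjusted p = 0.00436 and 0.00968, 0.00436 to 0.843 over its alternatives). *MRPL38* (0.62 ± 0.097), *MRPS35* (0.62 ± 0.098), *MRPL2* (0.69 ± 0.11) and *MRPS2* (0.51 ± 0.10) rose, *MRPS2* not with library sizes alone.

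Sterol and fatty acid synthesis genes were lower, and 4 of 36 tested members rose, 26 fell and 6 did not pass (5 rose and 26 fell adjusted over the list alone). The sterol synthesis list had a median of -0.85 (camera adjusted p = 2e-07, adjusted p = 0.333 with an estimated correlation) and one of -1.19 with library sizes alone. *HMGCS1*, which encodes an early enzyme of the mevalonate pathway, went from 88.3 ± 2.15 to 21.9 ± 1.6 CPM (-2.01 ± 0.098). *MVD* (-2.23 ± 0.13) and *CYP51A1* (-1.69 ± 0.10) and *SQLE* copy ENSDARG00000079946 (-2.40 ± 0.14), which encodes squalene epoxidase, fell with it. The other *SQLE* copy, ENSDARG00000063319, named after its value was seen, rose from 0.495 to 3.22 CPM (2.71 ± 0.32). Of yolk syncytial layer and lipoprotein genes, 12 of 35 tested members rose, 7 fell and 16 did not pass (13 rose and 7 fell adjusted over the list alone). The yolk list had a median of 0.11 (camera adjusted p = 0.293). *apoa4a* (0.72 ± 0.10), *ctsla* (0.82 ± 0.12) and *apoeb* (0.66 ± 0.12) rose, and the transferrin gene *tfa* (-0.57 ± 0.11) fell.

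Of DNA replication genes, 5 of 40 tested members rose, 16 fell and 19 did not pass (5 rose and 16 fell adjusted over the list alone). The replication list had a median of -0.21 (camera adjusted p = 0.0368, adjusted p = 0.843 with an estimated correlation) and one of -0.55 with library sizes alone. That call ended without control replicate 2 or SYP-3343 replicate 1 (adjusted p = 0.276 and 0.577, 0.00263 to 0.843 over its alternatives). *MCM3* (-0.66 ± 0.095), *TYMS* (-0.70 ± 0.11), *FEN1* (-0.70 ± 0.11) and *dhfr* (-0.75 ± 0.12) fell. Mitosis genes went the other way, and 18 of 39 tested members rose, 0 fell and 21 did not pass (19 rose and 0 fell adjusted over the list alone). The mitosis list had a median of 0.24 (camera adjusted p = 6.02e-05, adjusted p = 0.785 with an estimated correlation). With library sizes alone the mitosis median was -0.09 and the calls of the examples *NUSAP1* (0.48 ± 0.090), *ccnb3* (0.50 ± 0.097), *NCAPG* (0.45 ± 0.090) and *kif2c* (0.46 ± 0.10) ended. Of tailbud and presomitic mesoderm genes, 8 of 35 tested members rose, 5 fell and 22 did not pass (9 rose and 6 fell adjusted over the list alone). The tailbud list had a median of 0.19 (camera adjusted p = 0.0844) and was not called. The Notch-related genes *her15.1* (1.39 ± 0.093), *her12* (1.45 ± 0.10) and *dlc* (0.98 ± 0.093) and the fibronectin *FN1* copy ENSDARG00000006526 (1.38 ± 0.11) rose. Of maternal and early embryo transcripts, 4 of 22 tested members rose, 1 fell and 17 did not pass (4 rose and 1 fell adjusted over the list alone). The maternal list had a median of 0.27 (camera adjusted p = 0.0338, adjusted p = 0.675 with an estimated correlation) and one of -0.07 with library sizes alone. The maternal call ended without control replicate 1 (adjusted p = 0.0632) and with a filter of 1 CPM in at least 2 libraries (adjusted p = 0.0701), over a range of 0.0181 to 0.675 across its alternatives. The linker histone gene *H1-10* (2.21 ± 0.10) rose, and *GSC* (-0.50 ± 0.13) fell. The germ cell list had a median of 0.10 (camera adjusted p = 0.0613) and was not called. The risers *CXCR4* copy ENSDARG00000041959 (1.22 ± 0.11) and *CXCR4* copy ENSDARG00000057633 (1.07 ± 0.13) encode a chemokine receptor found in many cell types. Here 3 of 15 tested members rose, 0 fell and 12 did not pass (3 rose and 0 fell adjusted over the list alone), and the list was called without control replicate 1 or SYP-3343 replicate 2 (adjusted p = 0.0169 and 0.0148, 0.0148 to 0.675 over its alternatives). The germ cell list was also called with the filter of 1 CPM (adjusted p = 0.0496), with the replicate number as a block (0.0429) and by fry (0.0468).

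In the nervous system, genes of neural progenitors and glia and of early neurons were tested as separate lists. Of the former, 32 of 61 tested members rose, 6 fell and 23 did not pass (36 rose and 6 fell adjusted over the list alone). The progenitor list had a median of 0.36 (camera adjusted p = 2e-05, adjusted p = 0.675 with an estimated correlation) and one of 0.03 with library sizes alone. *nes* (1.95 ± 0.10), *SLC1A3* copy ENSDARG00000104431 (1.39 ± 0.11), *ascl1a* (1.22 ± 0.10) and *her4.1* (1.37 ± 0.12) rose. Of early neuron genes, 4 of 66 tested members rose, 32 fell and 30 did not pass (4 rose and 33 fell adjusted over the list alone). The neuron list had a median of -0.29 (camera adjusted p = 0.00026, adjusted p = 0.379 with an estimated correlation) and one of -0.62 with library sizes alone. *NEUROD6* copy ENSDARG00000020794 (-1.16 ± 0.097) and *ATP1B2* copy ENSDARG00000034424 (-1.34 ± 0.14) fell, while the proneural gene *neurog1* (1.96 ± 0.11) and *EBF2* (1.06 ± 0.11) rose. Of eye and lens genes, 6 of 51 tested members rose, 9 fell and 36 did not pass (6 rose and 9 fell adjusted over the list alone). The eye and lens list had a median of -0.09 (camera adjusted p = 0.351) and was not called, but fell past the threshold without control replicate 2 or SYP-3343 replicate 2 (adjusted p = 0.034 and 0.0353, 0.034 to 0.988 over its alternatives). *atoh7* (1.03 ± 0.13), a retinal ganglion cell factor, rose. *VSX1* (-0.52 ± 0.096) and *RPE65* copy ENSDARG00000007480 (-0.73 ± 0.14) fell. Of neural crest and pigment cell genes, 12 of 41 tested members rose, 10 fell and 19 did not pass (16 rose and 10 fell adjusted over the list alone). The pigment cell list had a median of 0.20 (camera adjusted p = 0.225). The melanosome genes *OCA2* (1.88 ± 0.13) and *TYRP1* copy ENSDARG00000029204 (1.3 ± 0.14) and *MYCN* (0.75 ± 0.090) rose, and the iridophore gene *pnp4a* (-1.70 ± 0.10) fell. The call of this *TYRP1* copy ended with robust estimation of the dispersion (adjusted p = 0.0712, against 9.23e-39 to 0.00147 in its other alternatives).

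Of epidermis, ionocyte and hatching gland genes, 33 of 56 tested members rose, 5 fell and 18 did not pass (35 rose and 5 fell adjusted over the list alone). The epidermis list had a median of 0.42 (camera adjusted p = 1.81e-06, adjusted p = 0.675 with an estimated correlation) and one of 0.09 with library sizes alone. The keratins *krt97* (2.46 ± 0.11) and *krt91* (1.71 ± 0.13) rose, and so did the hatching enzymes *he1.2* (2.15 ± 0.11) and *he1.1* (2.09 ± 0.14), which digest the egg envelope and whose near-identical copies can share reads. Of notochord, cartilage and sheath genes, 9 of 45 tested members rose, 21 fell and 15 did not pass (10 rose and 24 fell adjusted over the list alone). The notochord and cartilage list had a median of -0.25 (camera adjusted p = 0.0217, adjusted p = 0.686 with an estimated correlation) and one of -0.58 with library sizes alone. *MATN1* (-3.29 ± 0.13), *COL8A2* (-1.63 ± 0.10), *COL9A1* (-1.2 ± 0.10) and *acana* (-1.45 ± 0.12) fell. The collagen list had a median of -0.001 (camera adjusted p = 0.784) and a mean of -0.01, with a test direction above 0, and was not called. Of collagen and basement membrane genes, 7 of 38 tested members rose, 7 fell and 24 did not pass (7 rose and 7 fell adjusted over the list alone). Here *col6a1* (-0.70 ± 0.094) and *COL6A2* (-0.51 ± 0.092) fell, and *loxl2a* (0.55 ± 0.11) rose, though not with library sizes alone.

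Of skeletal muscle genes, 25 of 68 tested members rose, 11 fell and 32 did not pass (29 rose and 12 fell adjusted over the list alone). The skeletal muscle list had a median of 0.19 (camera adjusted p = 0.0968) and was not called, but was without SYP-3343 replicate 1 (adjusted p = 0.0215, 0.0215 to 0.829 over its alternatives). *CKMT2* copy ENSDARG00000069615 (-2.33 ± 0.15), a mitochondrial creatine kinase, and the troponin genes *TNNI2* copy ENSDARG00000035958 (-1.05 ± 0.10) and *TNNI2* copy ENSDARG00000045592 (-2.90 ± 0.38) fell, and the myosin chaperone factor *SMYD1* copy ENSDARG00000009280 (0.99 ± 0.092) rose. Of heart muscle genes, 11 of 41 tested members rose, 6 fell and 24 did not pass (11 rose and 8 fell adjusted over the list alone). The heart muscle list had a median of -0.003 (camera adjusted p = 0.359), while its mean, 0.21, and its test lay above 0. *tcap* (2.87 ± 0.11), *nppa* (1.18 ± 0.11) and *nppb* (2.21 ± 0.22) rose, of which the last pair encode natriuretic peptides.

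Of endothelium and vessel genes, 15 of 44 tested members rose, 5 fell and 24 did not pass (15 rose and 5 fell adjusted over the list alone). The endothelium list had a median of 0.20 (camera adjusted p = 0.0176, adjusted p = 0.686 with an estimated correlation) and one of -0.14 with library sizes alone, and was not called without control replicate 2 (adjusted p = 0.0844, 0.00322 to 0.686 over its alternatives). *VEGFA* copy ENSDARG00000103542 (1.44 ± 0.11), *NOTCH1* copy ENSDARG00000103554 (1.2 ± 0.11), *plxnd1* (1.27 ± 0.13) and *NOTCH1* copy ENSDARG00000052094 (1.03 ± 0.11) rose. Of erythroid genes, 14 of 39 tested members rose, 3 fell and 22 did not pass (16 rose and 4 fell adjusted over the list alone). The erythroid list had a median of 0.23 (camera adjusted p = 0.0205, adjusted p = 0.785 with an estimated correlation) and one of -0.10 with library sizes alone. The call ended without control replicate 2 or SYP-3343 replicate 2 (adjusted p = 0.0761 and 0.165, 0.00109 to 0.785 over its alternatives). The embryonic globin *hbbe3* (2.43 ± 0.16) and the heme synthesis genes *UROD* (1.01 ± 0.11) and *PPOX* (1.2 ± 0.14) rose, as did *KLF3* (1.1 ± 0.094). Of myeloid genes, 10 of 38 tested members rose, 2 fell and 26 did not pass (10 rose and 2 fell adjusted over the list alone). The myeloid list had a median of 0.25 (camera adjusted p = 0.0176, adjusted p = 0.785 with an estimated correlation) and one of -0.08 with library sizes alone. This call also ended without control replicate 2 or SYP-3343 replicate 2 (adjusted p = 0.141 and 0.0547, 0.00112 to 0.785 over its alternatives). *MFAP4* copy ENSDARG00000116066 (5.29 ± 0.47) rose from 11 to 330 counts summed over the libraries of each group, in a family of similar copies that can share reads. *MFAP4* copy ENSDARG00000090557 (-1.34 ± 0.18) and *MFAP4* copy ENSDARG00000088745 (-0.58 ± 0.20), named after their values were seen, were the falls of the list, and *CEBPA* (0.68 ± 0.091) rose.

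Of kidney, gut and liver genes, 12 of 35 tested members rose, 3 fell and 20 did not pass (12 rose and 3 fell adjusted over the list alone). The kidney, gut and liver list had a median of 0.33 (camera adjusted p = 0.00611, adjusted p = 0.675 with an estimated correlation) and one of -0.002 with library sizes alone. The phosphate transporters *SLC20A1* copy ENSDARG00000010641 (0.85 ± 0.091) and *SLC20A1* copy ENSDARG00000020114 (0.95 ± 0.11) and the sodium pump subunit *atp1a1a.4* (0.63 ± 0.088) rose, and *NEUROD1* (-0.82 ± 0.099), which is also a neuronal factor, fell. Of retinoic acid and thyroid genes, 5 of 33 tested members rose, 6 fell and 22 did not pass (6 rose and 7 fell adjusted over the list alone). The retinoic acid and thyroid list had a median of -0.08 (camera adjusted p = 0.604). *HOXB5* copy ENSDARG00000013057 (-0.75 ± 0.10) fell, and *PAX8* (0.64 ± 0.12), *CYP26A1* (0.51 ± 0.11) and *HOXD4* (0.59 ± 0.12) rose, though not with library sizes alone.

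The contrast rests on 2 libraries per group from a single exposure level and time. Genes whose symbol is shared by several identifiers, and overlapping or antisense genes, are uncertain, since neither the treatment of shared reads nor the use of strand in the counting is given in the sources used here.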

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

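No test in this part was chosen after the result was seen. Of 186 named genes, none reversed under any of these alternatives and 104 kept their call throughout, while of 43 lists, 38 never reversed and 11 kept their call throughout. The count of changed genes, 7225 as reported, was 4665 at an adjusted p of 0.01 (2626 higher and 2039 lower) and 1492 with an absolute log2 fold change of at least 1 (746 higher and 746 lower), by construction. With library size alone, 1405 genes were higher and 9384 lower, since the median of all genes moved to -0.35, and 24 named genes lost their call. RLE factors gave 7216 genes, upper-quartile factors 7504, no filter 6634, the CPM filter 7287, DESeq2 5948, limma-voom 7021, robust estimation 7256, the legacy fit 7013 and leaving out the 20 most abundant genes 7188. DESeq2 shared 5888 calls of the same sign, lost 1234 and gave no adjusted p for 103. With the replicate block there were 7248 genes and 24 lists, germ cells being added (adjusted p = 0.0429, 0.0148 to 0.675 over its alternatives). Same-numbered libraries did not deviate together across 22769 genes (r = -0.042). Leaving out 1 library at a time gave 5356 to 6726 genes (2873 to 3611 higher, 2483 to 3115 lower) and 19 to 25 lists, and 2 calls had the opposite sign without SYP-3343 replicate 2. Of 23 called lists, camera with an estimated correlation called 0, while 4 lists had an unadjusted p under 0.05. Of all 43 lists fry called 7, of which 6 were among the 23 and the other was germ cells. None of the lists whose direction reversed was called as reported, and the direction is that of the test, which can differ from that of the median. These medians are of the log2 CPM differences that camera and fry were given, not of edgeR's fold changes, and fry leaves them unchanged. For fatty acid oxidation the direction turned with fry (median -0.0222) and without control replicate 1, with medians of -0.0704 to -0.016 over the libraries left out. For collagens it turned with fry (median 0.0003 on this scale, as reported and with fry alike). For eye and lens it turned without control replicate 1 and without SYP-3343 replicate 1 (-0.203 to 0.0299 over the libraries left out), and so it did for the circadian clock (-0.154 to -0.0096). For retinoic acid and thyroid it turned without SYP-3343 replicate 1 (-0.145 to 0.0052). For the reversals the cause was not tested. Of the lists lost with an estimated correlation, sterol synthesis had an estimate of -0.023, so correlation between its genes did not end its call. Depth limits genes near the floor of 3 counts.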

Other observations

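Chosen only after the result was seen were the tests on the 4 added lists (photoreceptor genes, early retina genes, cytosolic and mitochondrial tRNA synthetases). So were the tests on scaling, on the share of eye cells, on short transcripts and on late-onset genes. The count of digestive enzyme genes in each control library, in place of their mean, by which 4 passed, was also chosen then. For slower development, the use of intervals of the later lists was not part of the rule written beforehand.

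Aminoacyl-tRNA synthetases load amino acids onto tRNAs, and their cytosolic and mitochondrial lists were not tested against each other. All 19 tested genes of the cytosolic list rose (19 adjusted over the list alone), with a median log2 fold change of 1.47 (95% interval 1.196 to 1.56) and 1.13 with library size alone. The largest of the examples, *IARS1* (2.61), went from 93.3 ± 4.95 to 570.3 ± 14.2 CPM (SD, n = 2), with *EPRS1* (1.92) and *KARS1* (1.61) beside it. *KARS1* and *GARS1* encode the mitochondrial enzyme too, and the cytosolic histidine enzyme is not among the 19. Of the 19 genes, 5 also belong to the integrated stress response list (*AARS1*, *CARS1*, *GARS1*, *SARS1* and *WARS1*). Of 16 genes of the mitochondrial list, the one named *HARS2* rose from 130.2 to 278.2 CPM, *PARS2* fell and 14 did not pass (1 rose and 0 fell adjusted over the list alone). The list's median was 0.05 (-0.12 to 0.18) and turned to -0.02 with upper-quartile factors and -0.28 with library size alone. In controls *HARS2* lay far above the next gene of its list, *IARS2* (42.9 CPM). Whether *HARS2* also encodes the cytosolic histidine enzyme was not tested, so its rise may not be one of a mitochondrial enzyme. With an estimated correlation, adjusted p = 0.225 for the cytosolic list.

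Interferon-related genes did not move together. Beside *isg15* and *irf3*, *IRF7* (log2 fold change 2.37 ± 0.15) and *mhc1uba* (2.27 ± 0.19) rose, while *mxa* (-0.02 ± 0.65) and *mxb* (0.32 ± 0.73) did not pass. These genes were chosen after their values were seen.

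Of 64 photoreceptor genes, 38 fell and 0 rose (42 fell adjusted over the list alone), with a median of -1.23 (-1.72 to -0.80), and adjusted p = 0.293 with an estimated correlation. Scaling of the libraries is argued against, since their median lay between -1.56 and -1.22 over 4 scalings, and so is a smaller share of eye cells as the whole cause but not in part, since the median of 12 early retina genes, of which 5 fell and 2 rose (6 and 2 adjusted over the list alone), was -0.20 (-0.47 to 0.05, and -0.53 with library size alone). Slower development in the exposed embryos stays open. The tailbud list was not called (adjusted p = 0.0844, 0.0605 to 0.675 over its alternatives). But 8 segmentation genes of that list had at most 19 counts in any library, so its missing call says little about a delay. Early neurons alone of the 5 later lists were called lower. Of the 5, 2 had a median under 0, and the rule written beforehand took fewer than 3 as against slower development. By that rule the count went against it. But only 2 of the 5 had intervals above 0, so the count was not beyond its spread. The use of intervals was not part of that rule. Dying cells in the exposed embryos may add to the changes, with a median log2 fold change of 0.813 for *cdkn1a*, *mdm2* and *CCNG1*. Embryos older than the stated 24 hours in all libraries stay open. The highest count of 8 segmentation genes was 19, and these counts had been seen before the rule was written. The rule also required at least 4 of 11 digestive enzyme genes above 1 CPM in the controls, and 7 of the 11 were matched in the table. By the mean of the controls 4 passed (*prss1*, *CPB1*, *ela2l* and *prss59.2*), which met the rule. In each control library 3 did (*prss1*, *CPB1* and *ela2l*), a count chosen after the result was seen. The 4th, *prss59.2*, had 1.755 and 0.627 CPM in control replicates 1 and 2.

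Ribosomal protein genes were higher in SYP-3343 with a preset correlation, though adjusted p = 0.675 with an estimated correlation, which was 0.91. Scaling of the libraries is argued against, since the lowest median over 4 scalings was 0.539. For better recovery of short transcripts, mitochondrial ribosomal proteins were taken as other small proteins, and their median was 0.073. That argues against it only if their transcripts are as short, and transcript lengths were not compared, so it stays open. An effect of the exposure, and a difference in stage or parents between the groups, stay open as untested, and the rise may reflect any of them.

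Genes at 0 in one group and with at least 20 counts in each library of the other numbered 13. Of these, 4 were at 0 in both control libraries, among them *igfn1.2* (106 and 61 counts in SYP-3343), which argues against late-onset genes not yet expressed in the exposed embryos as the cause of all 13, and 9 were at 0 in SYP-3343, among them *crygm2b* (76 and 73 counts in controls). The other pairings of the libraries gave 3 and 5 genes, so differences between single libraries, whatever their group, may account for part of the 13 and cannot be told apart from an effect of group. Single libraries did differ in this way, as *dnajc8* had 935 counts in control replicate 1 and 0 in the other libraries, and *atp5if1a* had 0 in control replicate 2 against 991 to 1071 elsewhere. Parents of different genotype stay open and were not tested.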
